A study of Mus musculus with 6 samples.

How the data were processed

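Poly(A)-selected RNA was sequenced from 6 lines of mouse embryo fibroblasts at passage 4, all of the C57BL/6 strain and all lacking p53. Per the labels, 3 lines were homozygous for a knock-in allele of MDMX (gene Mdm4) with the substitutions W201S and W202G, and 3 lines carried wild-type MDMX. Each line came from 1 embryo, so a replicate here is an embryo and the p-values measure the spread between lines of separate embryos. Litter, culture day and sequencing run were not given in the sources used here, so no batch term was fitted. Groups and line numbers were taken from the sample titles (SG1, SG2 and SG3, and WT3, WT9 and WT11).

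The deposited files hold whole-number counts of reads per gene, with gene positions, exon positions and strand, as featureCounts writes them. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36, aligned with STAR 2.5.2b to GRCm38, and assigned to genes with featureCounts from Subread 1.5.2, and DESeq2 was among the tools used. The counts are unnormalised. Annotation release, treatment of multimapping reads and strand setting were not given in the sources used here, so counts of genes that overlap, of antisense pairs and of near-identical copies are uncertain. All 6 files list the same 49315 Ensembl gene identifiers, with 0 rows that name no gene. Symbols came from GENCODE M21 (GRCm38), in which 48970 identifiers had a symbol and 345 had none. Of the identifiers found in that release, 91.4% had the same start and end there. Coordinates below are those of the files (GRCm38, counted from 1).

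Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with too few reads were removed with filterByExpr at its defaults, which left 16068 genes. Library sizes were scaled by TMM, and SG was tested against WT, 2-sided, with the quasi-likelihood test (glmQLFit, glmQLFTest) and no covariate. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Below, "adjusted p" of a gene means this edgeR value. Log2 fold changes are SG minus WT with a standard error (SE) taken as the log2 fold change divided by the square root of the F statistic. Levels are CPM (counts scaled by the TMM-adjusted library size), as mean ± SD over n = 3 lines per genotype. For Xist and the Y-linked genes, CPM per line are over the plain library total.

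For gene groups, 34 lists were fixed before the data were examined. They cover Wnt signalling, p53 targets, cell cycle, matrix, inflammation, stress, metabolism, growth factor and morphogen responses, imprinted genes, positional identity, other cell types, sex and RNA composition. The list of 4 targeted genes was not tested as a set. The other 33 were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, 2-sided, with Benjamini-Hochberg adjustment over lists. Camera with an estimated correlation and fry were alternatives. Beside each set test stands the number of members past the threshold over all genes and adjusted over the list alone. The TGF-beta and BMP list is an exception, and its member counts are not reported here. Genes within 10 Mb of Mdm4 or Trp53 were compared with all other tested genes by 2-sided Fisher's exact tests, adjusted over both windows. Each chromosome was tested as a set with camera. Principal components were computed on log2 CPM (prior count 2) of the 500 genes of highest variance.

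The genes named were chosen by a rule fixed before the data were examined. It takes the 4 targeted genes and 6 Wnt pathway genes (Axin2, Lef1, Tcf7, Ccnd1, Myc, Ctnnb1). It takes per direction the 10 largest log2 fold changes past the threshold, with an average log2 CPM of at least 1, a symbol that is no placeholder, and no overlap of the CPM of both genotypes. It takes up to 4 members past the threshold per list, or 2 members with the smallest unadjusted p where a set test passed with no such member, and the sex-linked genes per library. Some genes that the rule takes are not reported here. Other genes are named where they count among a list's members, and a few in the closing section were chosen after their values were seen, as said there.

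The fits were tested on simulated data. Counts were drawn for the 16068 genes with the means, library sizes and edgeR dispersions per gene of the real comparison. The 200 changed genes were picked among those with an average log2 CPM above 0, so recovery of lower genes was not tested. The quasi-likelihood test recovered 74.6% of 67 genes changed 1.5-fold, 94% of 67 changed 2-fold and 100% of 66 changed 4-fold. Of its 190 calls, 11 (5.8%) were false, against 36 of 219 (16.4%) for DESeq2 1.42.0, in a single draw from edgeR's own dispersions. In a second simulation a list of 20 genes raised 1.3-fold was called and 0 of the other 33 lists were. Genes were drawn independently of each other, so this does not show how often lists of correlated genes are called falsely.

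Alternatives fixed in advance were other scalings (RLE, upper quartile, total counts), no filter on low counts and a stricter one (at least 10 counts and 1 CPM in 3 libraries), DESeq2, limma-voom without and with quality weights, a robust prior, a minimum fold of 1.5, 1 surrogate variable (sva 3.50.0), removal of chromosomes X, Y and MT or of genes near Mdm4 and Trp53, windows of 5 and 20 Mb, and leaving out each library in turn. The legacy form of the edgeR fit was also planned, and in this version it is the default and equals the reported fit. Chosen after seeing the data were the non-legacy form, Xist as a covariate, and a fit without SG1 and WT9.

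Library totals ranged from 49317925 to 65457242 counts, and between 15699 and 16306 genes had at least 10 counts in a library. A group with 0 counts of a gene was given a floor of 3 counts over the group, which covers counting error only.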

Results

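MDMX is a p53 inhibitor that also binds casein kinase 1 alpha (CK1-alpha, gene Csnk1a1), a kinase that primes beta-catenin for degradation. The study asked which transcripts respond when the contact between MDMX and CK1-alpha is broken in cells without p53. Gene-level mRNA counts were available for 3 fibroblast lines with the binding mutant (SG1, SG2, SG3) and 3 with wild-type MDMX (WT3, WT9, WT11), each from a separate embryo. Total counts were 54852998, 64434605 and 58689254 in SG1, SG2 and SG3, and 49317925, 65457242 and 60467326 in WT3, WT9 and WT11. Between 23053 and 23781 genes had a count in a library, and mitochondrial transcripts took between 1.005% and 1.092% of the counts.

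Transcript levels of the mutated gene and its partners differed between genotypes by less than the spread between lines. Mdm4 (ENSMUSG00000054387, chromosome 1, 132959484 to 133030561) stood at 60.04 ± 3.36 CPM in SG and 60.4 ± 2.33 CPM in WT lines, a log2 fold change of -0.01 with an SE of 0.05 (adjusted p = 0.96). Csnk1a1 (ENSMUSG00000024576, chromosome 18, 61555274 to 61590061) stood at 406 ± 8.09 CPM in SG and 406 ± 7.52 CPM in WT, and Mdm2, which encodes the main ubiquitin ligase of p53, at 76.1 ± 5.17 and 77.3 ± 2.84 CPM. A change of 2 codons leaves no mark in a gene-level count, so Mdm4 does not check the labels. Trp53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873), which encodes p53, was counted at 71.4 ± 0.55 CPM in SG and 70.6 ± 2.19 CPM in WT. Counts per gene do not show which exons of the null allele were read, so Trp53 does not check the null background either.

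The lines of the 2 genotypes lay apart on the first principal component, in an order that was also that of their mean log2 CPM of Hox genes up to paralog 8 minus those from paralog 10. This component held 46.6% of the variance, with SG lines between -18.28 and -10.23 and WT lines between 5.74 and 22.85. The second held 27.6% and set SG1 (16.41) and WT9 (17.15) apart from the other 4 lines, which lay between -13.14 and -4.5. The same pair differed in sex-linked transcripts. Xist, the RNA that silences an X chromosome in female cells, was at 402 CPM in SG1 and 343 CPM in WT9, and between 0.562 and 0.71 CPM in the other 4. Ddx3y, a Y-linked helicase gene, was at 0.164 CPM in SG1 and 0.122 CPM in WT9 and between 93.4 and 98.6 CPM in the others, and Eif2s3y, Kdm5d and Uty divided the lines alike. Each genotype thus held 1 line with Xist and 2 with Y-linked transcripts. Correlations of log2 CPM were 0.9898 to 0.9937 within and 0.9865 to 0.9938 between genotypes, the highest being that of SG1 with WT9, so by correlation lines of 1 genotype were not closer to each other throughout.

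**Figure D1:**
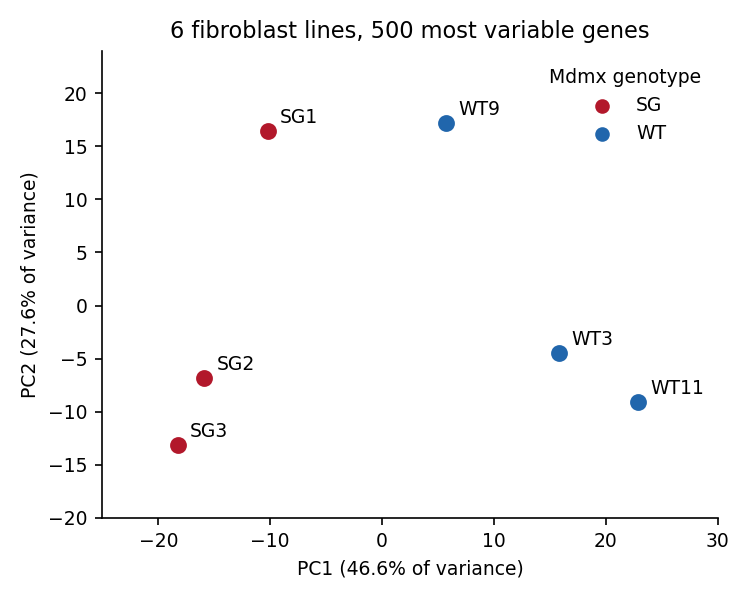
Position of each of the 6 lines on the first and second principal components of log2 CPM of the 500 most variable genes, coloured by genotype. SG lines lie below -10 and WT lines above 5 on the first component, while SG1 and WT9 lie above 16 on the second.

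Of the genes past the threshold, 130 were higher in SG lines, and the 10 with the largest rises under the fixed rule follow. The transcription factor gene Sim2 was at 90.2 ± 32.7 CPM in SG and 14.9 ± 4.8 CPM in WT, 6.03-fold higher (log2 fold change 2.59, SE 0.32, adjusted p = 0.0158). Esm1, which encodes the secreted proteoglycan endocan, was 6.58-fold higher (14.7 ± 3.19 against 2.23 ± 0.493 CPM, adjusted p = 0.00542). The homeobox gene Alx1, of craniofacial development, was 4.15-fold higher, and Eya2, a phosphatase and transcriptional coactivator, 3.64-fold higher. Arhgap36 was 8.47-fold higher with a wide spread (18.96 ± 14.3 against 2.23 ± 0.869 CPM, adjusted p = 0.039). The peptidase gene Enpep was 7.36-fold higher and Sorbs2, an adaptor of the actin cytoskeleton, 5.17-fold. Map3k7cl was 3.33-fold higher and Hoxa5 3.25-fold. Gzmb, a serine protease of cytotoxic lymphocytes, was 4.58-fold higher at a low level (3.72 ± 0.457 against 0.813 ± 0.471 CPM, adjusted p = 0.0322), in a family of similar genes that can share reads.

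Of the genes past the threshold, 176 were lower in SG lines, and the 10 with the largest falls under the fixed rule follow. Tfap2b, an AP-2 transcription factor of neural crest and limb, was 14.1-fold lower (0.585 ± 0.56 against 8.11 ± 2.63 CPM, log2 fold change -3.81, SE 0.55, adjusted p = 0.0229). Ahrr, the repressor of the aryl hydrocarbon receptor, was 8.46-fold lower. The homeobox genes Msx1 and Lhx2, both expressed in limb buds, were 5.74-fold and 5.6-fold lower. Tnn, which encodes tenascin-N of the matrix, was 5.53-fold lower (1.44 ± 0.825 against 7.94 ± 0.0395 CPM, adjusted p = 0.018). The adhesion genes Pcdhac2 and Pcdh10 were 4.95-fold and 3.4-fold lower, Pcdhac2 being part of a cluster whose members share exons. Bcl11b, a zinc finger transcription factor, was 3.77-fold lower (adjusted p = 0.00802), Sfn, which encodes 14-3-3 sigma, 3.67-fold, and the neutrophil chemokine gene Cxcl5 4.3-fold (adjusted p = 0.0493).

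In all, 306 of 16068 tested genes (1.9%) passed the threshold, 130 higher and 176 lower in SG, and 291 of them code for proteins. At least 2-fold changes numbered 44 higher and 66 lower, and the median absolute log2 fold change of the 306 was 0.74. The CPM of both genotypes did not overlap in any of the 306, and in 3404 tested genes (21.2%), where chance gives 10% on average over groupings. Genes move together, so the share in a single grouping can lie away from 10%. It was not computed for other groupings, so no excess is claimed. The count of 306 depends on single lines. It was 3 without SG2, 24 without WT3, 29 without WT11, 222 without SG3, 460 without WT9 and 579 without SG1. All of the 306 with a value kept their sign in each of these fits. This adds no support, because genes without overlap between genotypes keep their order when a line is left out. Of the 41 named genes past the threshold, 40 lost the call without SG2, 35 without WT3, 32 without WT11, 10 without SG3, 3 without SG1 and 0 without WT9, and 14 lost it with a robust prior, Sim2 and Tfap2b among them. Without SG1 and WT9, the lines with Xist, 703 genes passed, 273 of the 306 among them.

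**Figure D2:**
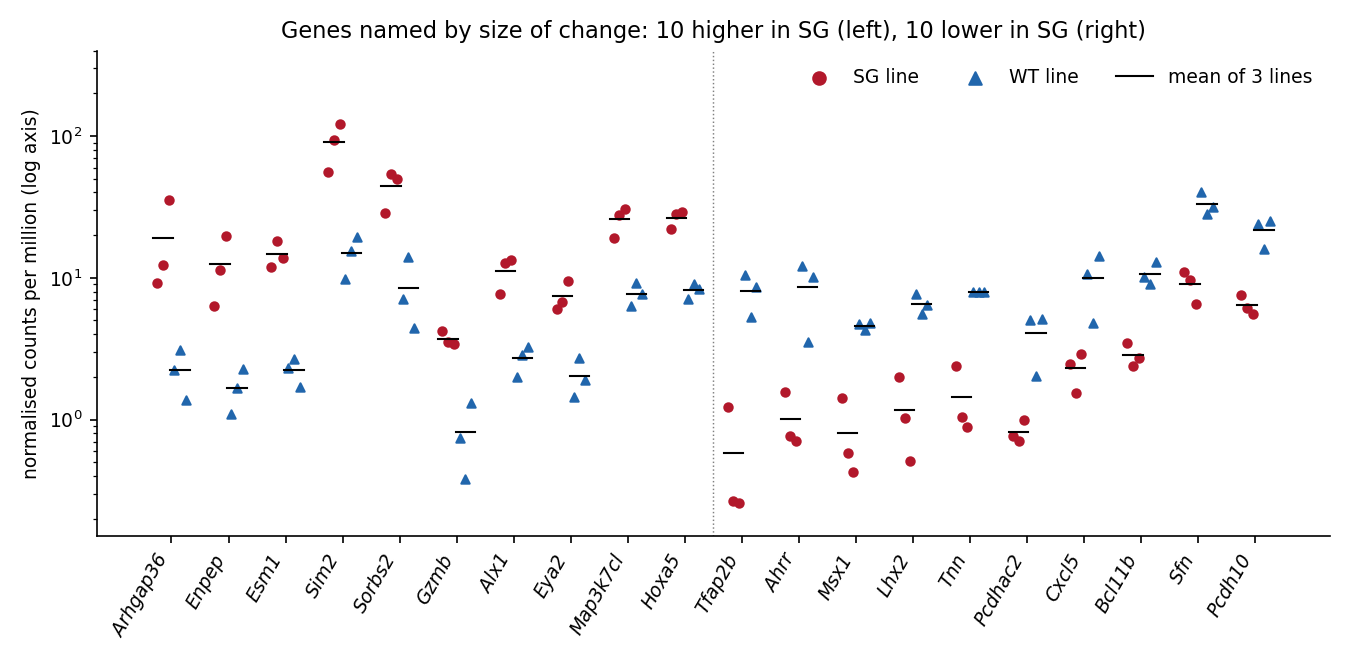
Normalised CPM (log axis) of the 10 genes with the largest rises and the 10 with the largest falls in SG lines, chosen by the fixed rule. Circles are SG lines, triangles WT lines and bars the mean of 3 lines. Lack of overlap between the genotypes was part of the rule, and means run from Sim2 at 90.2 against 14.9 CPM to Tfap2b at 0.585 against 8.11 CPM.

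Since CK1-alpha acts on beta-catenin, Wnt signalling was the first pathway examined. Among transcripts that beta-catenin raises in many cells, 1 passed the threshold. Apcdd1, a Wnt inhibitor and Wnt target, was 2.11-fold lower (15.6 ± 2.09 against 32.9 ± 7.87 CPM, log2 fold change -1.08, SE 0.18, adjusted p = 0.0322), a call lost without SG2, SG3, WT3 or WT11, with a robust prior (adjusted p = 0.0831) and at a minimum fold of 1.5 (adjusted p = 0.471). Axin2, the feedback inhibitor often used as a readout of the pathway, was at 2.12 ± 0.118 CPM in SG and 3.8 ± 0.761 CPM in WT (log2 fold change -0.83, SE 0.17) and missed the threshold over all genes (adjusted p = 0.0555). It passed in 6 of 23 alternatives, with adjusted p between 0.00112 and 1. Lef1, a transcription factor partner of beta-catenin, had a log2 fold change of -0.77 (SE 0.23, adjusted p = 0.151). Ctnnb1, which encodes beta-catenin, Ccnd1, Myc and Tcf7 had log2 fold changes of -0.02, -0.01, 0.01 and -0.12, none past the threshold, with SEs of 0.03, 0.09, 0.05 and 0.13.

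Over the 23 tested Wnt targets, 0 rose and 1 fell over all genes, a count that depends on the fit. It was 0 higher and 7 lower without a count filter or with DESeq2, 0 and 4 with Xist as a covariate or 1 surrogate variable, 1 and 5 without SG1 and WT9, and 0 and 0 with a robust prior or without SG2, WT3 or WT11. Wif1 was higher and 6 were lower (Apcdd1, Axin2, Twist1, Bmp4, Nkd2, Lef1) when adjusted over the list alone. The list's median log2 fold change was -0.12, and camera put it below other genes (adjusted p = 0.037, and adjusted p = 0.511 with an estimated correlation). Its camera call was also lost without SG1 (adjusted p = 0.0973), SG3 (0.0589) or WT11 (0.225). Of 34 Wnt ligands, receptors and modulators, only Ror2, a receptor of Wnt5a, passed over all genes, 1.23-fold lower (adjusted p = 0.0241). There were 5 higher, such as Sfrp1 and Fzd1, and 5 lower, such as Wnt7b and Fzd5, adjusted over the list alone, and the set test gave adjusted p = 0.891. Among 23 genes of the destruction complex and Wnt transducers, 0 passed either way (camera adjusted p = 0.419).

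The lists of genes that mark position in the embryo had the most members past the threshold. Of 37 tested Hox genes, 8 were higher in SG (Hoxa2 to Hoxa7, Hoxc4 and Hoxc5) and 1 lower (Hoxc10). The counts were 0 and 0 without SG2, 3 and 0 without WT3 or WT11, 5 and 0 without SG3, 11 and 4 without SG1, 8 and 4 without WT9, 9 and 8 without SG1 and WT9, 16 and 9 without a count filter, and 16 and 6 with DESeq2. Hoxa5 was at 26.6 ± 3.97 CPM in SG and 8.16 ± 1.01 CPM in WT (log2 fold change 1.70, SE 0.13, adjusted p = 0.00542), Hoxa6 at 5.24 ± 0.211 and 2.05 ± 0.143 CPM (1.36, SE 0.11, adjusted p = 0.00623), and Hoxa4 and Hoxa3 had log2 fold changes of 1.41 and 1.59. Adjusted over the list alone, 18 were higher and 11 lower. Toward the 5′ end of the clusters, whose genes pattern distal limb and tail, the 12 genes of paralog number 10 or more lay below 0, and Hoxc10 passed (log2 fold change -0.48, SE 0.09, adjusted p = 0.0476) while the others did not, such as Hoxa13 (log2 fold change -1.78, SE 0.39, adjusted p = 0.0652), Hoxd13 (-1.59, SE 0.45, adjusted p = 0.132) and Hoxc13 (-2.63, SE 0.83, adjusted p = 0.176). The size of the Hoxc13 fall rests on WT11, at 7.18 CPM against 1.46 in WT3 and 0.978 in WT9, with 0.171 to 0.705 in SG lines. Hoxc12 (6.05 CPM in WT11, 1.66 in WT3, 0.795 in WT9) and Hoxb13 (2.77, 0.28 and 0.352) were alike, while Hoxa13 and Hoxd13 were high in every WT line. The list's median log2 fold change was 0.27 and its mean -0.03, so these differ in sign. Camera placed it above other genes (adjusted p = 5.7e-06, and adjusted p = 0.249 with an estimated correlation), and without SG1 and WT9 its adjusted p was 0.234. The list's mean deviation of log2 CPM from the mean of all lines was 0.18, -0.03 and -0.15 in SG1, SG2 and SG3. In WT3, WT9 and WT11 it was 0.01, -0.06 and 0.06, so the genotypes overlapped and the list did not rise as a whole. Hoxa3, Hoxa4, Hoxa7, Hoxa2, Hoxc5 and Hoxc10 overlap exons of other genes, while Hoxa5, Hoxa6 and Hoxc4 do not.

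**Figure D3:**
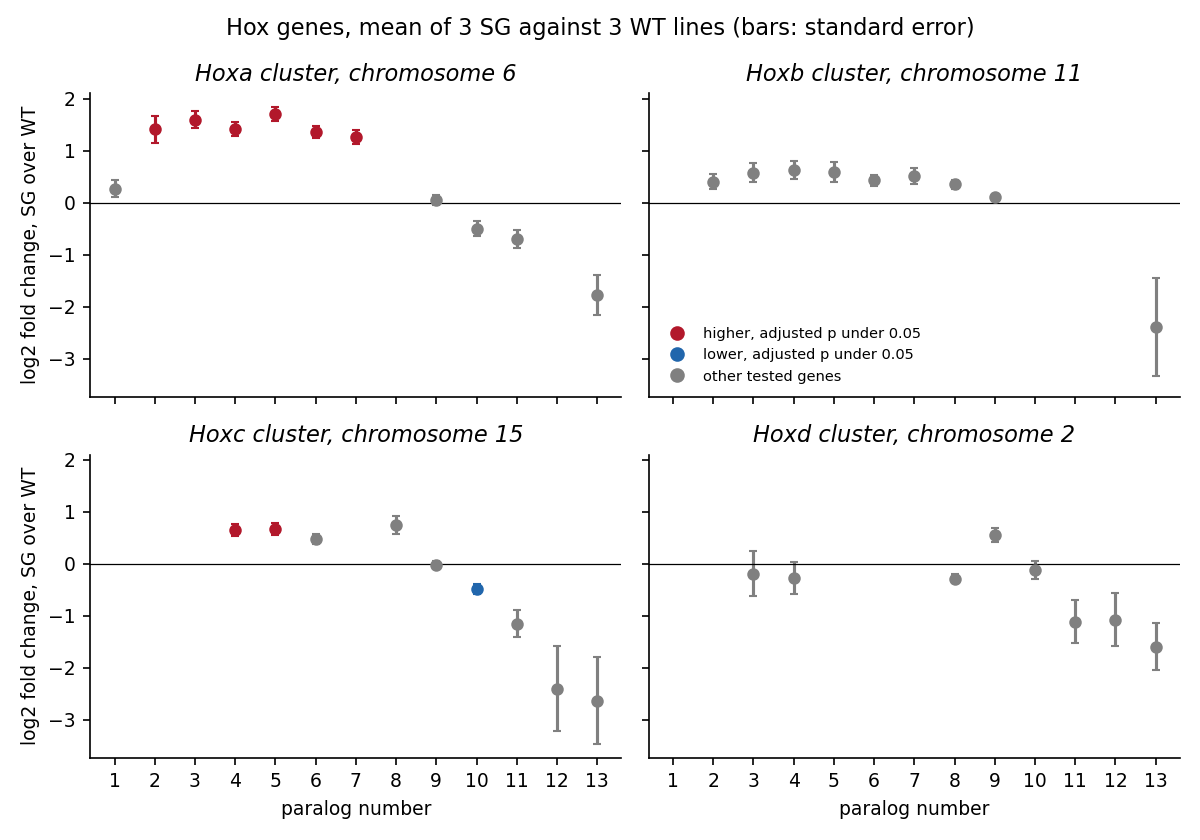
Log2 fold change (SG over WT, 3 lines each) of the 37 tested Hox genes against paralog number in each of the 4 clusters, with bars for the standard error and colour for genes past the threshold. Hoxa2 to Hoxa7 lie between 1.26 and 1.70, and all 12 genes of paralog number 10 or more lie below 0.

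Of 40 limb and axial patterning factors, 3 were higher, Alx1 and Meis2 among them, and 8 lower (Shox2, Twist2, Lhx9, Msx1, Lhx2, En1, Prrx1, Tbx15). Shox2, which acts in the proximal limb, was at 18.1 ± 0.47 CPM in SG and 26.4 ± 1.14 CPM in WT (log2 fold change -0.54, SE 0.05, adjusted p = 0.00802). Twist2, of dermal mesenchyme, and Lhx9, of limb and gonad, had log2 fold changes of -0.41 and -0.76 (adjusted p = 0.0183 and 0.0228). Prrx1, expressed throughout limb mesenchyme, was at 304 CPM in SG and 411 CPM in WT (log2 fold change -0.44, SE 0.08, adjusted p = 0.0445). Adjusted over the list alone, 8 were higher and 14 lower. Camera placed the list below other genes (median log2 fold change -0.13, adjusted p = 0.0104, and adjusted p = 0.511 with an estimated correlation), a call lost without WT9 (adjusted p = 0.138). Members past the threshold were 0 without SG2, 1 higher without WT3, 2 lower without WT11, and 7 higher and 13 lower without a count filter or with DESeq2.

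Of 26 tested cytokine, chemokine and protease genes, 17 had log2 fold changes below 0 and 9 above. Il1rl1, the receptor of interleukin 33, was at 386 ± 30.9 CPM in SG and 905 ± 179 CPM in WT, 2.34-fold lower (log2 fold change -1.23, SE 0.14, adjusted p = 0.0119). The monocyte chemokine gene Ccl7 was 2.49-fold lower (adjusted p = 0.0229), and Cxcl5 and Csf1, the macrophage growth factor, also fell. Cxcl12, a chemokine that retains blood progenitors, was 2.36-fold higher (912 ± 171 against 386 ± 76.3 CPM, adjusted p = 0.019). Over all genes 1 member rose and 4 fell (0 and 0 without SG2 or WT3, 0 and 2 without WT11, 1 and 9 without a count filter), and adjusted over the list alone 2 were higher and 8 lower. The list passed camera (median log2 fold change -0.16, adjusted p = 0.00496) and fry (adjusted p = 0.0127), in camera also without each library in turn, with adjusted p = 0.257 with an estimated correlation.

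Interferon-stimulated genes were below 0 in 27 of 29 cases (median log2 fold change -0.32) and 0 passed over all genes or adjusted over the list alone, with Ifit2 at -0.25 (adjusted p = 0.148) and Cxcl10 at -0.55 (adjusted p = 0.243). Camera gave adjusted p = 0.0104, and adjusted p = 0.769 with an estimated correlation, and the call was lost without SG2 (0.272) or WT3 (0.475). The list's mean deviation of log2 CPM was 0.59 in WT3 and 0.18 in WT9 but -0.34 in WT11, and -0.59 in SG2 but 0.06 in SG1 and 0.11 in SG3, so the genotypes overlapped. For macrophage and other blood cell markers the genotypes overlapped too, with a mean deviation of -0.14, -0.07 and 1.13 in SG1, SG2 and SG3 and of 0.28, 0.2 and -1.4 in WT3, WT9 and WT11. All 14 had log2 fold changes above 0 (median 0.56), 0 passed over all genes or adjusted over the list alone, and Cd14 and Cd68 had log2 fold changes of 0.62 (adjusted p = 0.339) and 0.56 (adjusted p = 0.388). Camera gave adjusted p = 0.0227, and adjusted p = 0.769 with an estimated correlation. The extremes were SG3 and WT11, with Lyz2, the macrophage lysozyme gene, at 28.3 CPM in SG3, 3.8 CPM in WT11 and 10.7 to 14.3 CPM in the other 4 lines, and the list's call was lost without SG3 (adjusted p = 0.511) or WT11 (0.454).

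Markers of the other cell types did not pass as sets with all 6 lines, while the epithelial list passed upward without SG3 (adjusted p = 5.23e-05), without WT3 (0.0473) and with no count filter (0.0362). For each of the lists of epithelial, endothelial, neural and glial, skeletal muscle, adipocyte, cartilage and bone, and pericyte markers, 0 members passed over all genes. Their camera adjusted p were 0.235, 0.996, 0.367, 0.265, 0.277, 0.594 and 0.532 in that order. Adjusted over the list alone, 2 neural and glial markers were higher (Nes and Elavl4) and 2 lower (Map2 and Sox2), 1 skeletal muscle marker was higher (Cdh15), 2 adipocyte markers were lower (Fabp4 and Lpl), 1 cartilage and bone marker was higher (Acan) and 1 lower (Runx2), and 0 of the epithelial, endothelial or pericyte markers passed. The adipocyte list's median (-0.02) and mean (-0.15) lay below 0 with 4 of 8 members above it. Sex-linked transcripts (adjusted p = 0.927), mitochondrially encoded transcripts (0.161) and histone genes (0.12) did not pass, with 0 members past the threshold over all genes or adjusted over the list alone.

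Among matrix genes single members rose, and the set did not pass. Fn1 (fibronectin), at 8884 ± 535 CPM in SG and 6723 ± 474 CPM in WT, was 1.32-fold higher (log2 fold change 0.40, SE 0.07, adjusted p = 0.0308). Sparc was 1.31-fold, Fbln2 1.27-fold and Col11a1, a collagen of cartilage, 1.78-fold higher, and no other of the 30 members passed over all genes. Without SG2, WT3 or WT11 0 members passed, and without a count filter 6 were higher and 7 lower. Adjusted over the list alone, 6 were higher, with Fbln5 and Lox added, and 6 lower (Col12a1, Thbs2, Fbln1, Postn, Col6a3, Col6a2). The set test gave adjusted p = 0.491. YAP/TEAD targets passed camera upward (median log2 fold change 0.09, adjusted p = 0.0227, and adjusted p = 0.746 with an estimated correlation) with 0 members past the threshold over all genes, and the call was lost without SG2 (0.125) or WT3 (0.165). Crim1, F3 and Amotl2 were higher and Dock5 lower adjusted over the list alone. Crim1, a binder of BMPs, had a log2 fold change of 0.54 (adjusted p = 0.0578) and Dock5 of -0.26 (adjusted p = 0.0551). Smooth muscle and myofibroblast genes did not pass (adjusted p = 0.178, 0 members).

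Proliferation and stress lists showed small shifts with 0 members past the threshold, over all genes or adjusted over the list alone. S-phase genes had a median log2 fold change of -0.05 (camera adjusted p = 0.037, and adjusted p = 0.769 with an estimated correlation), with Rrm2, a ribonucleotide reductase subunit, at -0.27 (adjusted p = 0.0679) and the helicase gene Mcm6 at -0.14 (adjusted p = 0.126). Mitotic genes were at -0.06 (camera adjusted p = 0.0312, and adjusted p = 0.769 with an estimated correlation), with the kinesin gene Kif11 at -0.11 (adjusted p = 0.247) and Cenpf at -0.08 (adjusted p = 0.312). ATF4-type stress genes were at -0.10 (camera adjusted p = 0.0312, and adjusted p = 0.769 with an estimated correlation), with Nupr1 at -0.31 (adjusted p = 0.179) and asparagine synthetase, Asns, at -0.16 (adjusted p = 0.309). All 3 calls were lost without SG1 (0.166, 0.212 and 0.113) or WT11 (0.386, 0.324 and 0.362), that of the S-phase genes without SG3 (0.0589) and that of the ATF4 genes without SG2 (0.311). Ribosome biogenesis, unfolded protein response and cholesterol synthesis genes gave camera adjusted p = 0.053, 0.253 and 0.235. The ribosome biogenesis list passed downward without SG2 (0.00249), WT3 (0.00236) or WT9 (0.017), with no count filter (0.0201) and with Xist as a covariate (0.0412), and the cholesterol list without WT9 (0.0046) and without SG1 and WT9 (0.0219).

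Of 26 p53 targets, 1 passed. Plk2, a polo-like kinase gene, was 1.52-fold higher in SG (470 ± 25.0 against 309 ± 27.7 CPM, log2 fold change 0.60, SE 0.07, adjusted p = 0.012), also adjusted over the list alone, and the set did not pass (adjusted p = 0.491, with a median of -0.01 and a mean of 0.03 of opposite sign). Egln3, an oxygen-sensing prolyl hydroxylase gene, was 1.56-fold higher as the 1 of 22 hypoxia and glycolysis genes to pass either way (set adjusted p = 0.666). The receptor kinase antagonist gene Spry2 was 1.56-fold higher as the 1 of 22 immediate early genes, 2 with Dusp5 adjusted over the list alone (set adjusted p = 0.16). The set of TGF-beta and BMP response genes did not pass (adjusted p = 0.16). Foxf2, a forkhead gene downstream of Hedgehog, was 1.71-fold lower, the 1 of 13 Hedgehog genes, with 1 higher and 2 lower over the list alone (set adjusted p = 0.12). Slc38a4, an imprinted amino acid transporter gene, was 1.29-fold higher, the 1 of 24 imprinted genes, with 8 higher, such as Igf2 and Dlk1, and 5 lower, such as Plagl1, adjusted over the list alone (set adjusted p = 0.12). Of the 33 lists, 10 passed camera at the preset correlation and 0 with an estimated one, and the 9 other ways to part the 6 libraries into 3 and 3 gave between 3 and 18.

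**Figure D4:**
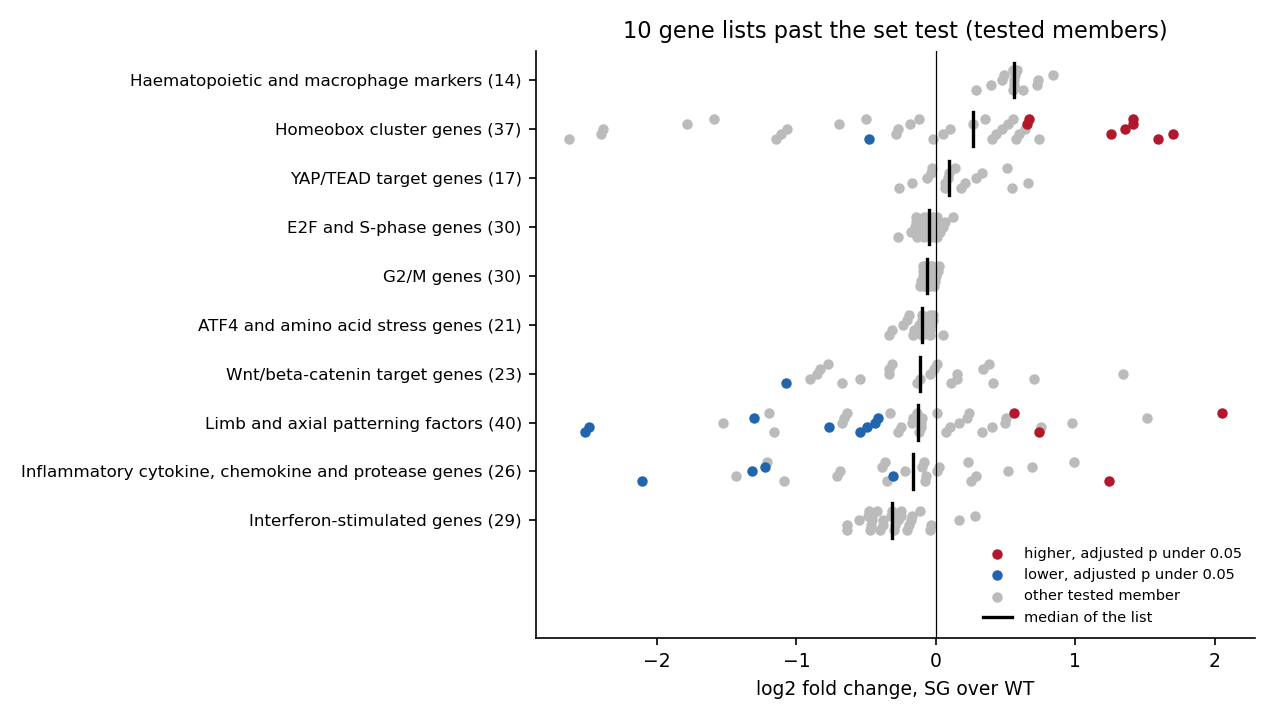
Log2 fold change (SG over WT, 3 lines each) of every tested member of the 10 lists past camera at the preset correlation, with the number of members in brackets, black bars for the median, and colour for members past the threshold over all genes. Medians run from -0.32 for interferon-stimulated genes to 0.56 for macrophage and other blood cell markers, and neither of these 2 lists has a member past the threshold.

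A knock-in can carry flanking chromosome from the stem cells it was made in, so genes around Mdm4 were compared with the rest. Within 10 Mb of Mdm4, 1 of 113 tested genes passed (0.88%, Lhx9), against 1.91% of all others (Fisher's exact test, adjusted p = 0.728). The share turned with the window, with 0 of 93 genes within 5 Mb (Fisher's exact test, unadjusted p = 0.427) and 6 of 172 within 20 Mb (3.49% against 1.89%, unadjusted p = 0.147). Within 10 Mb of Trp53, whose null allele is in both genotypes, 7 of 315 passed (2.22%, adjusted p = 0.728). No chromosome passed as a set. Camera called 0 of 20 chromosomes at an adjusted p under 0.05 (0 also at an unadjusted p under 0.05, the smallest being 0.135 for chromosome 12, and 0 with an estimated correlation). The largest median shift of an autosome in a library was 0.028 on the log2 scale. A gain from 2 to 3 copies in all cells would give 0.58 against a library without it. The shift was taken from the mean of all libraries, so a gain would give less than that, and one shared by all lines would not show.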

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

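The non-legacy fit, Xist as a covariate and the fit without SG1 and WT9 were chosen after seeing the data; the other alternatives were fixed before. No paired analysis was possible because the genotypes share only the line number 3, and the numbers name separate embryos. All 306 genes kept their sign wherever they had a value, which adds no support because their CPM did not overlap between genotypes. Between 287 and 338 genes passed under RLE, upper-quartile and total-count scaling, limma-voom, the non-legacy fit and without chromosomes X, Y and MT or the genes near Mdm4 and Trp53, 235 with a robust prior (14 of the 41 named calls lost), 267 with a stricter filter, 420 with 1 surrogate variable and 431 with Xist as a covariate. The surrogate variable was -0.573 in SG1, -0.581 in WT9 and between 0.277 and 0.298 in the other lines. It thus parts the lines as Xist does, and both fits make nearly the same adjustment. Without a filter 959 passed (421 higher, 538 lower, with prior degrees of freedom of 12.93 against 3.7), with DESeq2 952 (422, 530), with voom quality weights 568 (229, 339), without SG1 and WT9 703 (315, 388), and at a minimum fold of 1.5 only 8 (7, 1), which tests a stricter question. Leaving out 1 library gave 3 to 579 genes, 2 to 234 higher and 1 to 345 lower. Fewer libraries, and prior degrees of freedom between 3.53 and 4.1, stand behind these fits, and why SG2, WT3 and WT11 matter most was not tested.

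Of the 63 named genes none changed sign past the threshold in any alternative. With an estimated inter-gene correlation 0 lists passed camera. Adjusted p were 0.511 for Wnt targets and limb factors and 0.769 for the S-phase, G2/M, interferon, ATF4 and macrophage lists. They were 0.746 for YAP/TEAD targets, 0.257 for inflammatory genes and 0.249 for Hox genes. The estimates were 0.48, 0.563, 0.786, 0.58 and 0.944 for the S-phase, G2/M, interferon, ATF4 and macrophage lists and 0.165 for YAP/TEAD targets. They were 0.03 for limb factors, 0.014 for Hox genes, 0.004 for Wnt targets and -0.035 for inflammatory genes. For Wnt targets and inflammatory genes the estimate lay below the preset 0.01, so a higher correlation does not account for their loss. The unadjusted camera p went from 0.0112 to 0.0554 for Wnt targets. For Hox genes, with an estimate close to the preset, it went from 1.73e-07 to 0.00754. The 2 forms of camera thus differ by more than the correlation used, and a lost call does not by itself show correlated genes. What else differs was not tested. With fry 2 passed, inflammatory and Hox genes, against adjusted p of 0.162 for Wnt targets, 0.362 for S-phase and G2/M genes, 0.283 for YAP/TEAD targets, 0.193 for limb factors and 0.565 for interferon, ATF4 and macrophage genes. Without SG1 and WT9, S-phase (0.056), G2/M (0.0596) and Hox genes (0.234) did not pass, and the cause was not tested. Leaving out 1 library gave 5 to 15 lists, with adjusted p of 0.00531 to 0.225 for Wnt targets, 0.00942 to 0.386 for S-phase, 0.00607 to 0.324 for G2/M, 0.000869 to 0.165 for YAP/TEAD, 7.62e-10 to 0.475 for interferon, 5.23e-05 to 0.362 for ATF4, 0.00147 to 0.138 for limb and 0.001 to 0.511 for macrophage lists. The targeted genes, the chromosome test and the separation on the first component kept their side of the threshold or their order in each alternative run. Neither window passed in any, but the share near Mdm4 ran from 0% within 5 Mb to 3.49% within 20 Mb, turning from below to above that of other genes. Lists that passed only in an alternative, beyond the epithelial, ribosome biogenesis and cholesterol lists, were smooth muscle (0.000869), matrix (0.0412), immediate early (0.0246) and histone genes (0.0339), upward without WT9, Hedgehog genes downward without SG3 (0.0175) or a filter (0.0401), imprinted genes upward without a filter (0.0469), and, without SG1 and WT9, smooth muscle (0.00565), immediate early (0.00574) and imprinted genes (0.0493) upward. Depth limits genes under the count filter, such as Gzmk and Gzmn. Among the genes added without it, 7 passed.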

Other observations

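The genes first named in this part were chosen after their values were seen, as were the tests on granzymes, on sex, on overlapping Hox genes and on the number of genes called in other splits; the tests against the Hox index and on lists and chromosomes in other splits were set before their results were seen. Levels and adjusted p are from the same edgeR fit (3 lines per genotype), except that granzyme CPM are over the plain library total.

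Single genes outside the fixed lists also changed, and no set of them was tested. Slit3, a secreted guidance cue, was at 60.6 ± 5.37 CPM in SG and 130 ± 16.8 CPM in WT (log2 fold change -1.10, SE 0.10, adjusted p = 0.00802). The semaphorin and VEGF co-receptor gene Nrp2 had a log2 fold change of -0.74, Sema5a of -0.60, Sema6d of -0.91, Ntn4 of -0.71 and Flrt3 of -0.73, while the netrin receptor gene Neo1 (0.53) and the plexin gene Plxnb1 (0.46) were higher. Gdnf, a neurotrophic factor, and its receptor subunit gene Gfra1 were lower (-1.40, adjusted p = 0.0229, and -0.71, adjusted p = 0.00542), and the signalling receptor gene Ret was higher (1.02, adjusted p = 0.045). Thy1, a surface marker of fibroblasts, was at 280 ± 25.5 CPM in SG and 460 ± 19 CPM in WT (adjusted p = 0.00802), and Crabp1, which binds retinoic acid, at 361 ± 73.9 and 755 ± 138 CPM (adjusted p = 0.0295). The transcription regulator genes Irx1 (-1.23), Irx2 (-0.85), Tfap2a (-0.89) and Eya1 (-0.37) were lower and Foxc1 (0.81), Six4 (0.37) and Eya4 (0.41) higher.

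Of the granzyme and perforin genes, whose products kill target cells when released by lymphocytes, Gzmb, Gzmc, Gzmd, Gzmf, Gzmg and Prf1 were higher in SG at low levels. In the cluster on chromosome 14, Gzmc was at 1.41 ± 0.243 CPM in SG and 0.127 ± 0.0407 CPM in WT (adjusted p = 0.00623), Gzmd at 1.39 ± 0.109 and 0.365 ± 0.0778 CPM (adjusted p = 0.012) and Gzmg at 0.522 ± 0.0831 and 0.0225 ± 0.00726 CPM (adjusted p = 0.00736). Gzmf had 65 counts over the SG lines and 0 over the WT lines, at least 21.3-fold higher against a floor of 3 counts over the group. Prf1, the perforin gene on chromosome 10, was at 0.482 ± 0.027 CPM in SG and 0.0296 ± 0.013 CPM in WT (adjusted p = 0.00802). Gzma (adjusted p = 0.0583), Gzme (adjusted p = 0.52) and Gzmm (log2 fold change 0.09, SE 0.30, adjusted p = 0.921) did not pass, and Gzmk and Gzmn were removed by the count filter.

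The number of changed genes was set against other groupings of the libraries. Of the 10 ways to part 6 libraries into 3 and 3, only 1, the real one, gave as many as 306 genes, and the highest of the others gave 0, but 10 splits are too few for a share under 0.05. For the fixed lists at the preset correlation, 4 of the 10 splits gave as many as the real 10, and the split of SG1, SG2 and WT9 against the rest gave 18, the highest of the others. For chromosomes all 10 splits gave the same 0. The real count of lists was thus within the range that other groupings of the same lines gave, so it does not set the genotypes apart. For chromosomes there was no result to set against the splits. At 10 splits no share under 0.05 could have been reached in either case.

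Log2 fold changes of Hox genes followed paralog number, above 0 in 18 of 21 genes up to paralog 8 (8 passed, and Hoxd3, Hoxd4 and Hoxd8 were at -0.19, -0.27 and -0.28) and below 0 in the 12 from paralog 10 (1 passed). Across the 37 tested genes, which are not independent replicates, Spearman's rho of log2 fold change with paralog number was -0.76 (permutation p within clusters 1e-05, the smallest that 100000 permutations can give), with medians of 0.59 up to paralog 8 and -1.13 from paralog 10. Reads shared by overlapping or antisense genes were argued against by the 21 Hox genes without exon overlap (rho -0.89, permutation p = 2e-05), and sex, which was balanced between genotypes so that a fit with Xist as a covariate decides nothing, by the 4 lines without Xist alone (rho -0.76, permutation p = 1e-05), where the list's camera call was lost (adjusted p = 0.234). The mean log2 CPM of the low minus that of the high paralogs was 0.74, 1.34 and 1.96 in SG1, SG2 and SG3 and -0.49, 0 and -1.33 in WT3, WT9 and WT11 (exact permutation p = 0.1, the smallest possible), an order the lines also took on the first principal component, and limb and axial factors that followed this index between lines of 1 genotype also differed between genotypes (rho 0.78 across 40 genes, reached by 1 of 36 orders of the lines within genotypes, a share of 0.028 and the smallest possible). Because the index orders the lines as the first component does, a slope on it can follow any variation along that component. Wnt targets gave a rho of 0.5 by the same test, which was not run on genes at large. A different mix of body regions in each embryo's culture is thus a candidate explanation that these values allow but do not single out. An effect of the MDMX mutation on positional genes was not tested apart from it and stays open.

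Camera placed Wnt targets below other genes in SG at the preset correlation only (adjusted p = 0.511 with an estimated correlation), with 9 of 23 members above 0. That shift was also seen in the 4 lines without Xist alone (median log2 fold change -0.09, camera adjusted p = 0.0336 at the preset correlation, within a range of 0.00531 to 0.511 over this list's alternatives). Each genotype held the same number of lines with Xist, so a sex effect alike in both genotypes would not part them. So small a median, in a list that passes at the preset correlation only, does not decide whether sex acts differently by genotype. The mix of body regions was tested in the same way as for the limb factors. Across the 23 targets rho between log2 fold change and slope on the Hox index was 0.5, reached by 5 of 36 orders (a share of 0.139). For these targets, a regional mix and an effect of the mutation on beta-catenin signalling cannot be told apart here, because each genotype is 3 embryos and the orders are few.

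For the granzymes, lymphocytes or natural killer cells in the SG cultures were argued against by a list of 30 T cell and natural killer markers, whose summed level was 5.83 ± 2.27 CPM in SG and 5.92 ± 1.16 CPM in WT, a ratio of 0.985, while all granzymes and Prf1 summed to 11.8 ± 1.69 and 3.01 ± 1.03 CPM, a ratio of 3.93. This concerns the difference between genotypes. Per line, the marker sum was 8.46, 4.55 and 4.5 CPM in SG1, SG2 and SG3, and 5.6, 4.97 and 7.21 CPM in WT3, WT9 and WT11. Within each genotype it took the order of the granzyme and Prf1 sum given below. Such cells are therefore not excluded as a part of the spread between lines. Single markers had few counts and went both ways. Nkg7, with 45 counts over the SG and 23 over the WT lines, was at 0.256 ± 0.0992 and 0.137 ± 0.0584 CPM (log2 fold change 0.93, adjusted p = 0.361). Cd3e, with 13 and 25 counts, was at 0.0769 ± 0.0776 and 0.149 ± 0.103 CPM and was removed by the count filter. Reads moving between granzyme copies were argued against by the summed level of the 7 granzyme genes of chromosome 14, which was 3.97-fold higher (8.49 ± 1.14 against 2.14 ± 0.65 CPM, without overlap), and by Prf1, although which copy rose stays uncertain. All granzymes and Prf1 summed to 13.7, 11.3 and 10.5 CPM in SG1, SG2 and SG3, where the Hox index was 0.74, 1.34 and 1.96. The sum was 2.45, 2.38 and 4.2 CPM in WT3, WT9 and WT11, at an index of -0.49, 0 and -1.33. The sum thus did not rise with the index within either genotype. With few lines, this argues against the regional mix as far as that index measures it. Expression of these genes by the fibroblasts themselves may account for the rise and was not tested.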
